A study of Arabidopsis thaliana with 12 samples.

How the data were processed

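The series holds 12 arrays of Arabidopsis seedlings, 3 for each of 4 groups: Ler wild type and eid3, each kept dark or given a red pulse. Per the labels the 3 arrays of a group are biological replicas, seeds were stratified for 3 days at 6 °C, germination was induced by 2 h of red light, and seedlings grew at 21 °C. Groups were taken from the labels.

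Per the file headers, each array was scanned in 1 colour and quantified with Agilent Feature Extraction 10.5.1.1, and the deposited processed signal is a linear intensity after background subtraction and spatial detrending, with surrogate values for dim spots. No normalization between arrays had been applied to these intensities as deposited. The deposited series table held the same processed signals rounded to 3 significant digits, as checked against all 12 scanner files, with a ratio between 0.995 and 1.005. No spot was saturated. The median processed signal was between 232 and 302 per array.

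Each array held 45220 spots, of which 43803 were not controls. Control spots and spots that the scanner software marked as outliers were left out, and spots of the same probe were averaged, which gave 43603 probes. Per the file headers and annotation columns, 37540 probes named 1 locus code, 873 several and 5190 none, and 28595 of 29030 loci were found in the reference gene table. Probes naming several loci were tested but name no gene in the text. Genes were taken in the order of that table only to place them along chromosomes, and no coordinates are given, because the table and the array design rest on different builds.

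Values were log2 processed signals minus the 75th percentile of the array. A probe entered when it was well above background on all arrays of at least 1 group, and each gene was represented by the probe with the highest mean, which left 23888 genes. The linear model held the 4 groups without further terms and was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3. The 5 contrasts were the light response in each genotype, the genotype difference in each light condition, and their interaction. P values were adjusted by Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called. Tables and figures were made with Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9. A probe not well above background on any array of a group gives a bound, from the mean of the brighter group against, on each dimmer array, the higher of the probe's own signal and the lowest signal among probes well above background.

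Fixed before the data were examined were the groups, the design, the tests, the rule for naming genes and most alternatives. The gene lists were 19 lists written from general knowledge, with 412 loci, of which 393 were tested, and each list was tested in every contrast, 95 tests in all, by camera of limma with its preset correlation of 0.01 and again with an estimated correlation. Some lists share members, so their counts are not independent. The shade list shares IAA19, IAA29, ACS8 and XTH15 with the auxin, ethylene and expansin lists. HEMA1, GUN4, GUN5 and PORC are on both the early light-induced and the chlorophyll biosynthesis list. The text names, per contrast, genes among the 10 with the largest rise and the 10 with the largest fall whose groups did not overlap, up to 2 risers and 2 fallers per list, and 13 genes chosen in advance. For length it names fewer than the rule gives. The light score is the mean signed log2 value over genes called for the mean light effect, tested by fry of limma and by exact permutation; the larger spread of dark eid3 adds some covariance between the choice of these genes and the interaction. Clustering along chromosomes was tested with windows of 100 consecutive genes and 10000 random draws.

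The model was tested on simulated data, in which 200 of 23601 genes were changed. It recovered 65.7 percent of 2-fold and 89.4 percent of 4-fold changes in the wild type light response, and 49.3 and 80.3 percent in the interaction, with 12 and 6 unchanged genes called. The simulated noise was independent between genes and had the same spread for a gene on every array. It held no slide shift and no outlying array, so these rates do not cover such features of the real data.

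Alternatives were quantile normalization, normexp background correction with an offset of 50, no filter on dim probes, a filter on all 12 arrays, the replicate number as a block, slide as a block, eBayes with trend and robust fitting, each probe tested separately, the series table, fits over the 2 groups compared, stricter thresholds and leaving out each array in turn. Array quality weights, and slide as a block without dark eid3 replicate 3, were added after the data had been seen. The test of the interaction over 100 assignments of genotype was repeated later with the mean genotype and light effects taken out first.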

Results

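Gene expression was measured in seedlings of Arabidopsis thaliana, in the Landsberg erecta (Ler) wild type and in the mutant line eid3, whose altered gene the labels do not name. Seedlings grew for 4 days in darkness and then either stayed dark or received a red light pulse of 2 min at 30 µmol per square metre and second, followed by 45 min of darkness before harvest. The 4 groups were dark wild type, pulsed wild type, dark eid3 and pulsed eid3, with 3 arrays each from material that the labels call biological replicas. Each of the 12 arrays was a 1-colour Cy3 Agilent array, and between 70.0 and 76.0 percent of the spots per array lay well above background. The number of arrays limits the precision of every value below. Differences are given on the log2 scale with the standard error (SE) of the limma fit, as pulsed minus dark or eid3 minus wild type, with n = 3 arrays per group. After filtering, 23888 genes were tested in each of 5 contrasts.

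The arrays of a group lay close together except for 1. Within-group correlations over genes were between 0.992 and 0.998 in the other 3 groups and 0.997 between dark eid3 replicates 1 and 2, against 0.941 between these and dark eid3 replicate 3. On that array 2300 genes were over 2-fold higher and 1870 over 2-fold lower than the mean of the other 2. Touch, wound and rapid stress genes had a median deviation of 2.94 there, and 25 of the 31 members with a value on every array were over 2-fold higher. Auxin synthesis and response genes had a median deviation of -1.13 and shade and PIF target genes of -0.98. The deviation was -1.40 for seed storage and maturation markers, -0.78 for light-harvesting complex genes, 0.77 for heat shock genes and 0.53 for ethylene synthesis and signalling genes. This array was kept, because the design fixed before the data were examined uses all 12, and values without it are given beside the results that it moved.

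**Figure D1:**
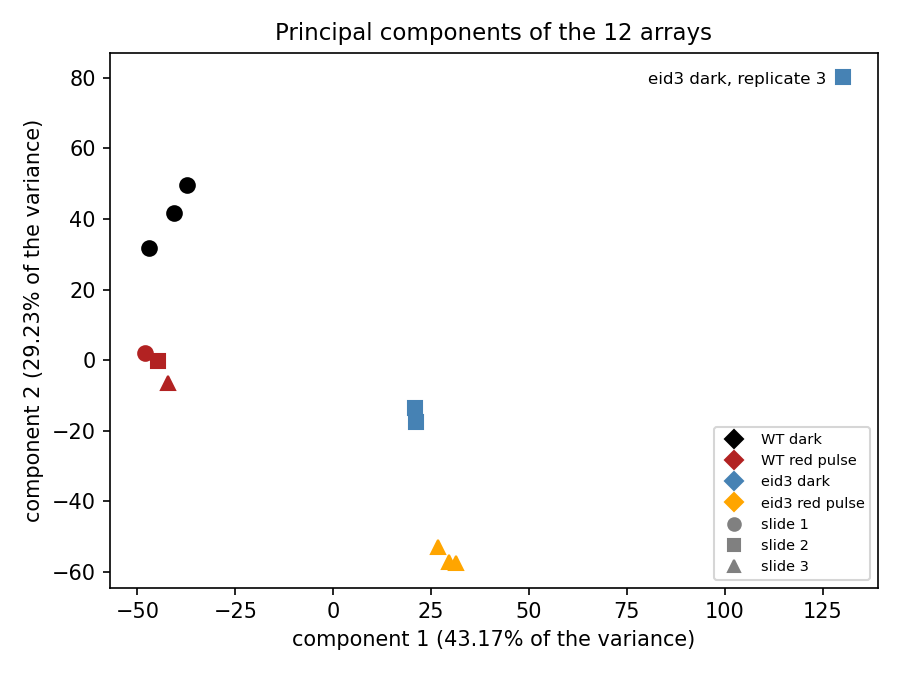
Principal components 1 and 2 of the 12 arrays, in units of the component scores, with colour for the group and marker shape for the slide. Component 1 held 43.2 percent and component 2 held 29.2 percent of the variance; the genotypes separate along component 1, and dark eid3 replicate 3 lies at 130 on it, away from the other 2 dark eid3 arrays at 20.9 and 21.1.

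The arrays came from 3 slides that overlap the groups. Slide 1 held the dark wild type arrays and pulsed wild type replicate 1, slide 2 the dark eid3 arrays and pulsed wild type replicate 2, and slide 3 pulsed wild type replicate 3 and the pulsed eid3 arrays. With slide as a block the light response in wild type is a within-slide value of slide 1 and the genotype difference after the pulse a within-slide value of slide 3. The genotype difference in darkness is then linked through the pulsed wild type arrays, and no slide holds both eid3 groups. Per the file headers, slides 1 and 2 were scanned on the same day and slide 3 on another. The dark and pulsed eid3 arrays were thus scanned on different days, and scan day cannot be told apart from slide there. In that fit each of these within-slide values rests on 1 pulsed wild type array. Its 6 residual degrees of freedom come from dark wild type, dark eid3 and pulsed eid3, 2 each, and 0 from pulsed wild type, so its p values borrow the spread of other groups. Counts of list members called in the blocked fit are given for each comparison. Dark eid3 had a median SD over genes of 0.24, against 0.092 in dark wild type, 0.099 in pulsed wild type and 0.062 in pulsed eid3, so the shared spread understated its error, and fits over the 2 groups alone are given beside the counts.

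The first comparison asks which genes the pulse changed in wild type seedlings. HY5 (AT5G11260), a bZIP transcription factor that promotes photomorphogenesis, rose by 2.86 ± 0.09 (limma adjusted p = 8.85e-08), and its homologue HYH (AT3G17609) by 2.48 ± 0.18. SIG5 (AT5G24120), a sigma factor of the plastid RNA polymerase, rose by 5.54 ± 0.13, and ELIP1 (AT3G22840) and ELIP2 (AT4G14690), thylakoid early light-induced proteins, rose by 4.66 ± 0.16 and 3.97 ± 0.38. PIL1 (AT2G46970), a bHLH gene known for its rapid response to shade, had a log2 difference of -4.95 ± 0.29 (limma adjusted p = 4.86e-06). The microRNA gene MIR163 (AT1G66725) rose by 6.17 ± 0.20. Where a gene was not above background on any array of a group, only a bound is given, from that group's background level: GA2OX1 (AT1G78440), whose product inactivates gibberellins, was at least 73.9-fold higher after the pulse, and BBX32 (AT3G21150) at least 108-fold higher.

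Among 24 measured light signalling regulators 11 rose and 2 fell, and the counts were the same adjusted over the list alone. SPA1 (AT2G46340), a partner of the ubiquitin ligase COP1, rose by 3.02 ± 0.11 and the GATA factor CGA1 (AT4G26150) by 3.09 ± 0.10, while FHY1 (AT2G37678), which carries phytochrome A to the nucleus, had a difference of -0.73 ± 0.08. All 8 early light-induced chloroplast genes were measured, 7 rose, and 8 rose adjusted over the list alone. Of 28 B-box zinc finger genes 14 rose and 2 fell (15 and 4 adjusted over the list alone), among them BBX25 (AT2G31380) with 5.33 ± 0.14, BBX31 (AT3G21890) with 5.35 ± 0.68 and BBX30 (AT4G15248) with 7.13 ± 0.39, the last above background on 1 of the 3 dark arrays. Of 25 circadian clock genes 15 rose and 0 fell (16 and 1 adjusted over the list alone), including PRR9 (AT2G46790) with 3.70 ± 0.27, ELF4 (AT2G40080) with 3.12 ± 0.13, LHY (AT1G01060) with 2.17 ± 0.14 and CCA1 (AT2G46830) with 2.07 ± 0.20.

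Shade and PIF target genes moved the other way. Of 15 measured members 10 fell and 0 rose (12 fell adjusted over the list alone), among them the homeodomain genes ATHB4 (AT2G44910) with -4.21 ± 0.37, HAT3 (AT3G60390) with -2.86 ± 0.22 and ATHB2 (AT4G16780) with -2.09 ± 0.24. HFR1 (AT1G02340) did not pass, with a log2 difference of -0.46 ± 0.31 (limma adjusted p = 0.485, and 0.00834 without dark eid3 replicate 3). Of 43 auxin genes 1 rose and 3 fell, the same counts adjusted over the list alone, with IAA29 (AT4G32280) at -3.47 ± 0.47 and IAA19 (AT3G15540) at -1.10 ± 0.27. Of 21 brassinosteroid genes 0 rose and 4 fell (1 and 7 adjusted over the list alone), with BEE3 (AT1G73830) at -2.14 ± 0.07 and PRE6 (AT1G26945) at -1.88 ± 0.16. In ethylene synthesis and signalling 0 of 22 rose and 4 fell (1 and 6 adjusted over the list alone). There ACS8 (AT4G37770), an ACC synthase gene, was at least 3.67-fold lower and ACS5 (AT5G65800) stood at -1.31 ± 0.19. Gibberellin metabolism and signalling genes split, with 2 of 20 higher and 2 lower, the same counts adjusted over the list alone, and the DELLA gene GAI (AT1G14920) at -1.24 ± 0.20.

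Genes of the photosynthetic apparatus and of flavonoid synthesis rose in part. Of 21 light-harvesting complex genes 9 rose and 0 fell (12 and 0 adjusted over the list alone), with LHCB2.2 (AT2G05070) at 2.24 ± 0.27. Of 33 photosystem, electron transport and RuBisCO genes 8 rose and 0 fell (15 and 0 adjusted over the list alone), and of 17 chlorophyll biosynthesis genes 6 rose and 1 fell (7 and 2 adjusted over the list alone). GUN4 (AT3G59400) stood at 1.52 ± 0.13 and GUN5 (AT5G13630), a subunit of magnesium chelatase, at 1.46 ± 0.09, against -0.87 ± 0.18 for PORB (AT4G27440), a protochlorophyllide oxidoreductase. Of 16 flavonoid and phenylpropanoid genes 6 rose and 0 fell (7 and 0 adjusted over the list alone), led by F3H (AT3G51240), a flavanone hydroxylase, with 4.79 ± 0.19, while CHS (AT5G13930), chalcone synthase, rose by 1.13 ± 0.21. In the photoreceptor list 2 of 14 rose and 1 fell (5 and 1 adjusted over the list alone): CRY3 (AT5G24850) stood at 2.61 ± 0.20 and PHYB (AT2G18790) at -0.84 ± 0.07, and PHYA (AT1G09570) did not pass, with -0.28 ± 0.16 (limma adjusted p = 0.39, and 0.00807 without dark eid3 replicate 3).

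Heat shock genes included 4 of 14 that rose and 0 that fell, the same adjusted over the list alone, with the heat stress factor HSFA2 (AT2G26150) at 2.47 ± 0.34 and HSP70-4 (AT3G12580) at 1.97 ± 0.19. Of 32 touch, wound and rapid stress genes 3 rose and 0 fell, the same adjusted over the list alone, among them CBF3 (AT4G25480) with 5.03 ± 0.50. Of 24 expansin and xyloglucan endotransglucosylase genes 0 rose and 1 fell, also over the list alone, XTH15 (AT4G14130) with -1.0 ± 0.06, which is also on the shade list. Seed storage and maturation markers had 0 of 15 and root and root hair markers 1 of 11 members that passed; in the root list this member fell, and 1 rose and 1 fell adjusted over the list alone.

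In all, limma called 1891 genes in wild type at an adjusted p under 0.05, 1127 higher and 764 lower after the pulse, and 643 of them changed at least 2-fold. The 3 arrays of each group did not overlap in 8765 genes, where chance separates 10 percent. Camera with its preset correlation called 14 of the 19 lists in this contrast, with adjusted p = 2.13e-15 for the early light-induced chloroplast genes (mean 2.3, within slide 1 2.15) and 3.2e-12 for the shade and PIF targets (mean -1.80, within slide 1 -1.79). For these lists adjusted p = 0.167 and adjusted p = 0.295 with an estimated correlation, and none of the list calls in any contrast held with an estimated correlation over all 12 arrays. That of the shade and PIF targets held in both light responses without dark eid3 replicate 3 (camera adjusted p = 0.0256 in each). Leaving out dark eid3 replicate 3, which enters here only through the shared spread, gave 5673 genes, and leaving out dark wild type replicate 2 gave 1161. Through that spread 5 auxin genes were then called higher and 21 lower, 11 and 5 touch, wound and rapid stress genes, and 1 and 12 brassinosteroid genes. The counts were 6 and 3 for photoreceptors, 4 and 4 for gibberellin, 1 and 7 for ethylene and 3 and 4 for expansin genes, 17 and 0 for photosystem genes and 2 and 2 for root markers, and also 15 and 6 for B-box genes, 7 and 2 for chlorophyll biosynthesis, 18 and 1 for clock genes, 1 and 13 for shade targets and 1 and 0 for seed markers. The touch list was then called (camera adjusted p = 0.034; adjusted p = 0.456 with an estimated correlation). The blocked fit called 671 genes, 455 higher and 216 lower. The fit over the 2 groups alone called 3103. In the blocked fit the calls of HSFA2, IAA29, GAI, GA20OX3 (AT5G07200), PORB, CHS and IAA19 ended (limma adjusted p between 0.059 and 0.369). Blocked calls of list members were 5 higher among early light-induced chloroplast genes, 9 among clock genes, 3 among light-harvesting, 2 among photosystem and 2 among flavonoid genes. There were 10 higher and 1 lower each among light signalling and B-box genes, and 7 lower among shade targets. Others were 3 higher in chlorophyll biosynthesis, 1 and 1 among photoreceptors, 2 higher among touch genes, 1 higher each among heat shock, gibberellin and root genes, 3 lower each among ethylene and brassinosteroid genes and 1 lower each among auxin genes and expansins. The blocked list calls of limma also ended for auxin (camera adjusted p = 0.237) and ethylene (camera adjusted p = 0.0809). The touch list gained a call in the blocked fit (camera adjusted p = 0.0302), which did not hold with an estimated correlation (camera adjusted p = 0.926).

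The second comparison asks the same of eid3. HY5 rose by 2.18 ± 0.09 (limma adjusted p = 4.86e-07; 2.26 with slide as a block) and SPA1 by 2.98 ± 0.11. PIL1 stood at -5.07 ± 0.29 and ATHB4 at -4.59 ± 0.37. BBX30, not above background on any dark eid3 array, was at least 106-fold higher after the pulse. SIG5 rose by 3.86 ± 0.13, ELIP1 by 2.87 ± 0.16 and ELIP2 by 1.80 ± 0.38 (limma adjusted p = 0.0126). HSFA2 rose by 4.11 ± 0.34 and HSP70-4 by 3.29 ± 0.19.

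The directions of the lists in eid3 were those seen in wild type for the groups with most changes. Light signalling regulators had 11 of 24 members that rose and 1 that fell (11 and 3 adjusted over the list alone), including GLK2 (AT5G44190), a regulator of chloroplast development, with 2.62 ± 0.13. Circadian clock genes had 15 of 25 that rose and 0 that fell (18 and 0 adjusted over the list alone), with PRR9 at 4.45 ± 0.27 and LHY at 0.93 ± 0.14. B-box genes had 15 of 28 higher and 4 lower (16 and 5 adjusted over the list alone), with BBX31 at 6.49 ± 0.68 and BBX23 (AT4G10240) at -3.29 ± 0.29. Early light-induced chloroplast genes had 7 of 8 that rose (8 adjusted over the list alone), flavonoid and phenylpropanoid genes 10 of 16 (10 adjusted over the list alone) and heat shock genes 9 of 14 (11 adjusted over the list alone), with 0 that fell in each. Shade and PIF targets had 9 of 15 members that fell and 0 that rose (12 fell adjusted over the list alone), with IAA29 at -3.35 ± 0.47. Ethylene genes had 6 of 22 that fell and 0 that rose, the same adjusted over the list alone, with ACS5 at -2.71 ± 0.19.

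Of the light-harvesting complex genes 3 of 21 rose in eid3 (4 adjusted over the list alone) and of the photosystem list 7 of 33 (10 adjusted over the list alone), with 0 that fell in either. PSBS (AT1G44575) stood at 0.98 ± 0.12. Chlorophyll biosynthesis had 6 of 17 members higher and 2 lower (7 and 4 adjusted over the list alone), with PORA (AT5G54190) at -1.24 ± 0.30 and PORB at -0.81 ± 0.18. Photoreceptors had 4 of 14 higher and 1 lower (7 and 1 adjusted over the list alone), with PHOT2 (AT5G58140) at 1.18 ± 0.18 and PHYB at -1.06 ± 0.07. Auxin genes had 2 of 43 higher and 3 lower (5 and 5 adjusted over the list alone), gibberellin genes 3 of 20 higher and 2 lower (3 and 3), brassinosteroid genes 0 of 21 higher and 3 lower (0 and 3), and expansin and xyloglucan endotransglucosylase genes 0 of 24 higher and 3 lower (1 and 3), with the counts adjusted over the list alone in parentheses. Seed markers had 0 of 15 members that passed and root markers 2 of 11 that rose (3 adjusted over the list alone). Of the touch, wound and rapid stress genes 3 of 32 rose and 1 fell, the same adjusted over the list alone, with DREB2A (AT5G05410) at 2.15 ± 0.11 and JAZ7 (AT2G34600) at -1.55 ± 0.25. That list depended on dark eid3 replicate 3, without which 18 of its members rose and 2 fell and its mean went from -0.25 to 0.72. Also without that array 5 auxin genes rose and 19 fell and the list mean went from -0.06 to -0.39. In that fit 7 gibberellin genes rose and 5 fell, 2 brassinosteroid genes rose and 10 fell, 4 expansin genes rose and 6 fell, and 6 photoreceptors rose and 3 fell. Of the light-harvesting genes 5 then rose, with the list mean at 0.19 in place of 0.45, and the photosystem list had 7 that rose and 1 that fell with a mean of 0.14 in place of 0.26. The photoreceptor mean went from 0.23 to 0.10 and the ethylene mean from -0.64 to -0.30, and both list calls ended. The mean of chlorophyll biosynthesis went from 0.04 to 0.10, that of brassinosteroid genes from -0.24 to -0.40, that of expansins from -0.05 to -0.03, that of seed markers from 0.14 to -0.29 (1 rose) and that of root markers from 0.05 to -0.06. In that fit 3 light signalling regulators, 7 B-box genes and 1 clock gene fell, beside 11, 15 and 17 that rose, and 1 ethylene gene rose. List calls gained in that fit of limma were touch (camera adjusted p = 6.84e-07; adjusted p = 0.157 with an estimated correlation), auxin (camera adjusted p = 0.00018; adjusted p = 0.431 with an estimated correlation) and brassinosteroid (camera adjusted p = 0.00653; adjusted p = 0.218 with an estimated correlation).

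In eid3 limma called 2866 genes, 1871 higher and 995 lower, 938 of them at least 2-fold, and 8221 genes had groups that did not overlap, where chance gives 10 percent. Of the genes called, 934 were higher in both genotypes, where 88.3 would be shared by chance, and 388 were lower in both, where 31.8 would be; 6 were called in opposite directions. Leaving out dark eid3 replicate 3 gave 6563 genes, and leaving out pulsed eid3 replicate 1, 2 or 3 gave 1664, 1716 and 1790. With slide as a block 440 genes were called, 2855 of the 2866 kept their direction, and of 46 genes called by name the calls of 24 ended, including ELIP2, BBX31, BBX32, IAA29 and ATHB4. Blocked calls of list members were 2 higher among early light-induced chloroplast genes, 6 among clock genes, 9 among light signalling regulators, 3 among heat shock and 2 among flavonoid genes. There were 7 higher and 2 lower among B-box genes, and 4 lower among shade targets. Others were 3 lower among ethylene and 2 among brassinosteroid genes, 1 lower each among photoreceptors, auxin genes and expansins, and 1 higher among touch genes. In the light-harvesting, photosystem, chlorophyll biosynthesis, gibberellin and root lists none of the calls remained. The fit over the 2 groups alone called 1359 genes. The heat shock list had a mean of 1.57 (camera adjusted p = 5.59e-07; 1.65 with slide as a block; adjusted p = 0.378 with an estimated correlation). The shade and PIF target list had a mean of -1.85 (camera adjusted p = 4.49e-11; -1.77 with slide as a block; adjusted p = 0.295 with an estimated correlation).

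The third comparison sets the genotypes side by side in darkness. Genes of the light-harvesting complexes, which bind chlorophyll at the photosystems, were higher in dark eid3: 19 of 21 rose and 1 fell (20 and 1 adjusted over the list alone), with LHCB1.4 (AT2G34430) at 4.15 ± 0.31 (limma adjusted p = 2.04e-05) and LHCB1.5 (AT2G34420) at 3.6 ± 0.26, and LHCB4.3 (AT2G40100) at -0.46 ± 0.10. Photosystem, electron transport and RuBisCO genes rose in 28 of 33 cases and fell in 0 (30 and 0 adjusted over the list alone), with PSBQ2 (AT4G05180) at 2.32 ± 0.17. Early light-induced chloroplast genes rose in 7 of 8 cases, the same adjusted over the list alone, with ELIP1 at 1.87 ± 0.16, ELIP2 at 2.82 ± 0.38 and GUN4 at 1.58 ± 0.13. Flavonoid and phenylpropanoid genes rose in 9 of 16 cases and fell in 1, the same adjusted over the list alone, with F3H at 3.31 ± 0.19 and CHS at 2.57 ± 0.21; 9 rose and 5 fell without dark eid3 replicate 3. MYB75 (AT1G56650), a regulator of anthocyanin synthesis, was at least 4.81-fold higher. PORA, the protochlorophyllide oxidoreductase of dark-grown seedlings, stood at -1.59 ± 0.30. In the fit with slide as a block 8 light-harvesting, 6 photosystem, 4 early light-induced, 3 chlorophyll biosynthesis and 2 flavonoid genes were still called higher and none lower (14, 20, 6, 3 and 2 higher adjusted over the list alone, with 3 chlorophyll biosynthesis genes lower). Among the lists that follow, 1 light signalling regulator, 1 B-box gene, 1 brassinosteroid gene, 1 gibberellin gene and 2 root markers were called higher there and 2 expansins lower. None of the auxin, ethylene, clock, shade, photoreceptor and seed calls in darkness remained.

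Some genes were measured in 1 genotype only. DDB1B (AT4G21100), a homologue of damaged DNA-binding protein, was at least 138-fold higher in dark eid3 and at least 144-fold higher after the pulse, and the transporter gene ABCB13 (AT1G27940) was at least 7.26-fold higher in darkness. LPAT3 (AT1G51260), a lysophosphatidyl acyltransferase gene, was at least 8.52-fold lower in dark eid3 and TRM23 (AT4G25430) at least 7.1-fold lower (limma adjusted p = 0.0744 with slide as a block). In all, 25 genes were above background on all 6 eid3 arrays and on 0 wild type arrays, and 20 genes on all 6 wild type arrays and on 0 eid3 arrays.

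Light signalling regulators in darkness had 8 of 24 members higher and 2 lower in eid3 (9 and 2 adjusted over the list alone), with CGA1 at 2.08 ± 0.10, LAF1 (AT4G25560) at 1.39 ± 0.23 and COP1 (AT2G32950) at -0.23 ± 0.07. HY5 stood at 0.98 ± 0.09 and HYH at 1.08 ± 0.18. B-box genes had 7 of 28 higher and 5 lower (10 and 5 adjusted over the list alone), with BBX25 at 2.18 ± 0.14, and clock genes 2 of 25 higher and 5 lower, the same adjusted over the list alone, with LHY at 1.60 ± 0.14. Chlorophyll biosynthesis had 8 of 17 higher and 3 lower (8 and 4 adjusted over the list alone). Auxin genes had 2 of 43 higher and 10 lower (2 and 9 adjusted over the list alone), with GH3.1 (AT2G14960) at -2.48 ± 0.41, whose call ended with slide as a block, and brassinosteroid genes 2 of 21 higher and 8 lower (2 and 11 adjusted over the list alone), with BR6OX1 (AT5G38970) at -1.35 ± 0.36. Expansin and xyloglucan endotransglucosylase genes had 2 of 24 higher and 9 lower (2 and 10 adjusted over the list alone), with XTH5 (AT5G13870) at -1.55 ± 0.15 and TCH4 (AT5G57560) at 1.80 ± 0.26. Gibberellin genes had 2 of 20 higher and 5 lower and ethylene genes 5 of 22 higher and 3 lower, both the same adjusted over the list alone, with GA3OX1 (AT1G15550) at -2.10 ± 0.42, GA20OX2 (AT5G51810) at 1.63 ± 0.18 and ACO4 (AT1G05010) at 2.19 ± 0.24. Several of these lists depended on dark eid3 replicate 3. Without it 10 auxin genes were higher and 14 lower, and the list mean went from -0.47 to -0.14 and its median from -0.49 to 0.03. Clock genes then had 10 higher and 5 lower, with a mean of 0.21 in place of 0.01, light signalling regulators 14 and 3, and gibberellin genes 7 and 6 with a mean turned from -0.07 to 0.05. B-box genes had 12 and 6 with a mean of 0.25 in place of 0.16, and brassinosteroid genes 4 and 11 with -0.10 in place of -0.27. Ethylene genes had 7 and 5, their mean went from 0.37 to 0.04 and the ethylene list call ended.

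Shade and PIF targets had 2 of 15 members higher and 3 lower in dark eid3, photoreceptors 2 of 14 higher and 0 lower, seed markers 2 of 15 higher and 0 lower, each the same adjusted over the list alone, and root markers 4 of 11 higher and 3 lower (4 and 4 adjusted over the list alone). The shade targets had 8 higher and 3 lower without dark eid3 replicate 3, and their mean turned from -0.16 to 0.14. In that fit photoreceptors had 7 higher and 0 lower with a mean of 0.26 in place of 0.13, and seed markers 4 and 0 with 0.50 in place of 0.07. Of the heat shock genes 1 was then lower, with the list mean at -0.33 in place of -0.13. List calls gained without that array were photoreceptors (limma camera adjusted p = 0.0182; adjusted p = 0.393 with an estimated correlation) and expansins (limma camera adjusted p = 0.0329; adjusted p = 0.218 with an estimated correlation). PIL1 had a log2 difference of -0.58 ± 0.29 (limma adjusted p = 0.164), PHYB of -0.12 ± 0.07 (limma adjusted p = 0.253) and PHYA of 0.15 ± 0.14 (limma adjusted p = 0.46). HFR1 had -0.04 ± 0.31 (limma adjusted p = 0.94) and, without dark eid3 replicate 3, 0.41 (limma adjusted p = 0.0113). Heat shock and touch, wound and rapid stress genes had 0 members that passed, also over the list alone; at an unadjusted level limma gave 10057 genes under 0.05 in this contrast. The touch list still had a mean of 0.89 (camera adjusted p = 0.00673; adjusted p = 0.779 with an estimated correlation), and without dark eid3 replicate 3 the mean was -0.09 (camera adjusted p = 0.887), with 4 members higher and 7 lower.

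In darkness limma called 7393 genes, 2918 higher and 4475 lower in eid3, 1933 of them at least 2-fold, and 10594 genes had groups that did not overlap, where chance gives 10 percent. Without dark eid3 replicate 3 it called 11744 genes, and 7172 of the 7393 were among them in the same direction. The fit over the 2 groups alone called 3094. The blocked fit called 545 genes, and 7364 of the 7393 kept their direction. Of 40 genes called by name all 40 kept their direction in the blocked fit and the calls of 22 ended, among them HY5, HYH, LHY, ELIP2, PORA and MYB75. The light-harvesting list had a mean of 1.89 (camera adjusted p = 7.78e-14; 1.71 with slide as a block; adjusted p = 0.308 with an estimated correlation) and the photosystem list a mean of 0.96 (camera adjusted p = 4.52e-18; 0.84 with slide as a block; adjusted p = 0.308 with an estimated correlation). The flavonoid list had a mean of 1.03 (camera adjusted p = 0.000234; 0.83 with slide as a block; adjusted p = 0.346 with an estimated correlation), and its call ended without dark eid3 replicate 3 (camera adjusted p = 0.141).

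The fourth comparison sets the genotypes side by side after the pulse. Light-harvesting complex genes were again higher in eid3, with 19 of 21 that rose and 0 that fell (20 and 0 adjusted over the list alone) and LHCB1.4 at 3.56 ± 0.31 (limma adjusted p = 4.91e-05; 3.4 within slide 3). Of the photosystem list 26 of 33 rose and 0 fell (27 and 0 adjusted over the list alone), with PSBO2 (AT3G50820) at 1.88 ± 0.19 and 1.70 within slide 3. Flavonoid genes had 11 of 16 higher and 1 lower, the same adjusted over the list alone, with CHS at 3.06 ± 0.21 and 2.78 within slide 3. SIG5 was lower in eid3 with -1.03 ± 0.13, and ELIP1 did not differ beyond its error, with 0.08 ± 0.16 (limma adjusted p = 0.742). The NAC gene NAC077 (AT5G04400), above background only on the 3 pulsed wild type arrays, was at least 6.94-fold lower in eid3. ACS5 stood at -2.79 ± 0.19 and ACO4, an ACC oxidase gene, at 2.1 ± 0.24.

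Among the other lists after the pulse, early light-induced chloroplast genes had 4 of 8 higher and 1 lower, light signalling regulators 4 of 24 higher and 1 lower, B-box genes 7 of 28 higher and 3 lower and clock genes 2 of 25 higher and 2 lower. Chlorophyll biosynthesis had 7 of 17 higher and 4 lower, and gibberellin genes 2 of 20 higher and 3 lower. All 6 of these counts were the same adjusted over the list alone. HEMA1 (AT1G58290) stood at 0.66 ± 0.07, PORA at -1.85 ± 0.30, BBX22 (AT1G78600) at 1.32 ± 0.09 and GA20OX1 (AT4G25420), a gibberellin oxidase gene, at -2.72 ± 0.32. Expansin and xyloglucan endotransglucosylase genes had 2 of 24 higher and 6 lower (2 and 7 adjusted over the list alone), with XTH33 (AT1G10550) at -1.61 ± 0.13. Auxin genes had 1 of 43 higher and 6 lower (1 and 5), shade targets 1 of 15 higher and 3 lower (2 and 3), ethylene genes 5 of 22 higher and 3 lower (6 and 3) and brassinosteroid genes 3 of 21 higher and 3 lower (3 and 4), with the counts adjusted over the list alone in parentheses. Heat shock genes had 5 of 14 higher and 0 lower and photoreceptors 1 of 14 higher and 1 lower, both the same adjusted over the list alone. Touch, wound and rapid stress genes had 3 of 32 and seed markers 3 of 15 higher (2 in each adjusted over the list alone) and 0 lower. Root markers had 2 of 11 higher and 1 lower, the same adjusted over the list alone, with the phosphate transporter gene PHT1-1 (AT5G43350) at 2.55 ± 0.24 and the root hair gene COBL9 (AT5G49270) at 1.77 ± 0.21.

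After the pulse limma called 6571 genes, 3209 higher and 3362 lower in eid3, 1638 of them at least 2-fold, and 14804 genes had groups that did not overlap, where chance gives 10 percent. Leaving out dark eid3 replicate 3, which enters only through the shared spread, gave 12490 genes, and leaving out pulsed eid3 replicate 2 gave 4289. In the fit without dark eid3 replicate 3, 9 auxin genes were called higher and 20 lower, 16 and 6 touch, wound and rapid stress genes, 13 and 7 B-box genes, 8 and 5 clock genes, 8 and 2 light signalling regulators and 3 and 8 shade targets. It called 11 and 5 ethylene genes, 6 and 6 gibberellin genes, 5 and 10 brassinosteroid genes and 2 and 14 expansin genes. It also called 11 and 4 flavonoid genes, 8 and 0 heat shock genes, 4 and 1 photoreceptors, 4 and 3 seed markers and 2 and 3 root markers. The touch list was then called (camera adjusted p = 0.0182; adjusted p = 0.431 with an estimated correlation). Within slide 3, the fit with slide as a block called 2447 genes, and the fit over the 2 groups alone 12004. In the blocked fit the calls of MYB75, HYH, HSFA2, HSP17.8 (AT1G07400), PHYB and HY5 ended (limma adjusted p between 0.078 and 0.199). Blocked calls were 13 higher among light-harvesting, 16 among photosystem and 4 among flavonoid genes, with 0 lower, and 2 higher and 1 lower among early light-induced chloroplast genes. B-box genes had 6 higher and 2 lower, chlorophyll biosynthesis 2 and 3, brassinosteroid genes 2 and 2, ethylene genes 2 and 1, auxin genes 1 and 2, and clock and gibberellin genes 1 and 1 each. Light signalling regulators and root markers had 2 higher, touch, heat shock and seed genes 1 higher each, and expansins 3 lower. The light-harvesting list had a mean of 1.59 (camera adjusted p = 8.06e-13; 1.49 within slide 3; adjusted p = 0.308 with an estimated correlation). The heat shock list had a mean of 0.59 (camera adjusted p = 0.027; 0.70 within slide 3; adjusted p = 0.773 with an estimated correlation), and its call ended without dark eid3 replicate 3 (camera adjusted p = 0.0512), without pulsed wild type replicate 3 (camera adjusted p = 0.0871) and without pulsed eid3 replicate 3 (camera adjusted p = 0.0689).

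**Figure D2:**
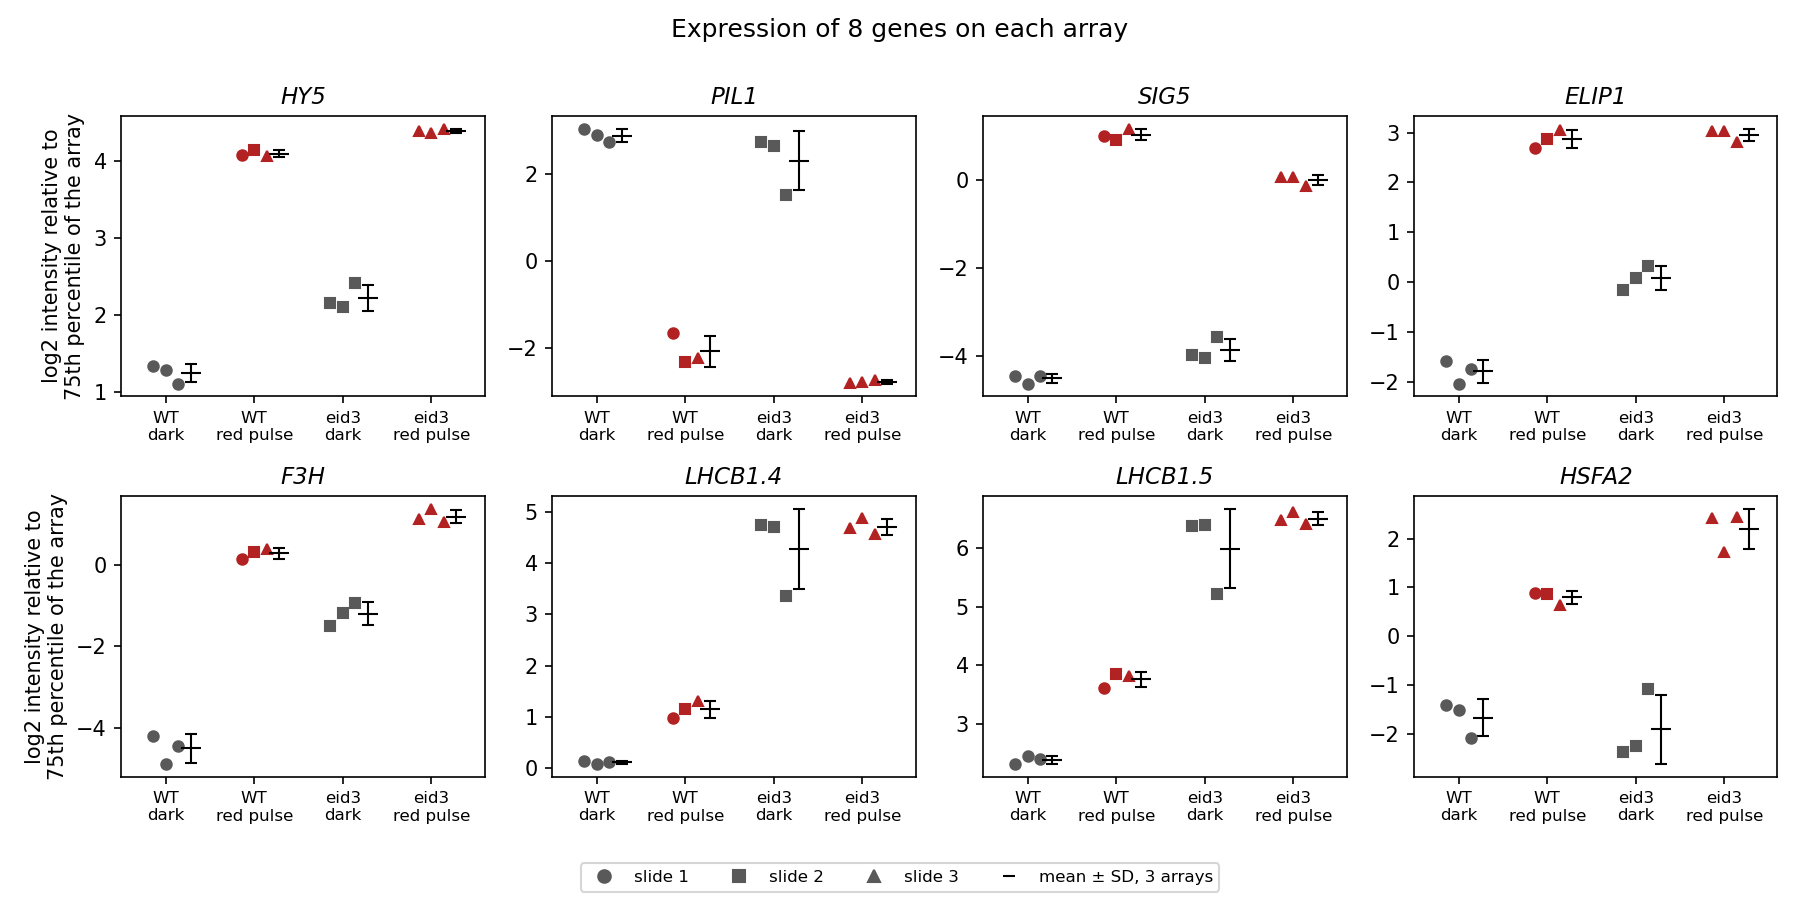
Log2 intensity of 8 genes relative to the 75th percentile of each array, per array, in the 4 groups; points are arrays with marker shape for the slide, and bars are the mean and SD of 3 arrays. HY5 and PIL1 moved in opposite directions after the pulse in both genotypes, and LHCB1.4 was 4.15 log2 units higher in dark eid3 than in dark wild type.

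The fifth comparison asks whether the light response itself differed between genotypes, by the interaction of genotype and light. SIG5 rose less in eid3 than in wild type, with a difference between the responses of -1.68 ± 0.18 (limma adjusted p = 0.00802; -1.92 with slide as a block). ELIP1 rose less by -1.79 ± 0.22 (limma adjusted p = 0.0118; -1.79 with slide as a block), F3H by -2.41 ± 0.27, CGA1 by -2.01 ± 0.14 and BBX25 by -1.68 ± 0.19. These 5 genes were all higher in eid3 in darkness, SIG5 by 0.65, a value looked up after its interaction was seen. The dark difference enters the interaction with a minus sign. Genes named for a negative interaction therefore tend to be higher in dark eid3 by this choice alone. RPT2 (AT2G30520), a phototropism signalling gene, had the difference -1.93 ± 0.10 (limma adjusted p = 9.46e-05; -1.94 with slide as a block). Other genes responded more in eid3: UGT84A1 (AT4G15480), a glycosyltransferase gene, with 2.37 ± 0.20, the kinase gene MAPKKK17 (AT2G32510) with 1.95 ± 0.20 and CYP86A7 (AT1G63710), a cytochrome P450 gene, with 2.16 ± 0.21.

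By list, early light-induced chloroplast genes had 3 of 8 members with a smaller response in eid3 and 0 with a larger one (5 and 0 adjusted over the list alone), and the list mean was -0.91 (camera adjusted p = 5.03e-10; -0.82 with slide as a block; adjusted p = 0.222 with an estimated correlation). Light-harvesting and photosystem genes had 0 of 21 and 0 of 33 members that passed in limma, where 2019 of all genes had an unadjusted p under 0.05; adjusted over the list alone 1 was higher and 3 lower in the former and 0 passed in the latter. Their means were -0.30 (camera adjusted p = 0.00129; -0.22 with slide as a block; adjusted p = 0.691 with an estimated correlation) and -0.12 (camera adjusted p = 0.000411; -0.10 with slide as a block; adjusted p = 0.74 with an estimated correlation). The blocked limma call of the light-harvesting list ended (camera adjusted p = 0.0622). These 2 lists had lower means without dark eid3 replicate 3. In that fit 1 light-harvesting gene was higher and 7 lower with a mean of -0.56, and 0 photosystem genes were higher and 1 lower with a mean of -0.24. Heat shock genes had 0 of 14 members that passed, 3 adjusted over the list alone (2 that passed without dark eid3 replicate 3), and a mean of 0.72 (camera adjusted p = 0.000501; 0.66 with slide as a block; adjusted p = 0.647 with an estimated correlation). Chlorophyll biosynthesis had 1 of 17 members lower, GUN5 with -0.80 ± 0.13 (2 adjusted over the list alone), and a list mean of -0.24 (camera adjusted p = 0.000102; -0.16 with slide as a block; adjusted p = 0.328 with an estimated correlation).

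B-box genes had 1 of 28 members higher and 2 lower (2 and 3 adjusted over the list alone), BBX22 with 1.05 ± 0.13, BBX25, and BBX18 (AT2G21320) with -0.94 ± 0.14. BBX18 was not above background in darkness in either genotype, so its value rests on fitted dark signals. The list had 2 higher and 4 lower without dark eid3 replicate 3, and its mean turned from 0.01 to -0.08. Light signalling regulators had 1 of 24 lower, CGA1 (2 adjusted over the list alone), and clock genes 1 of 25 lower, LHY with -1.24 ± 0.20, the same adjusted over the list alone (3 lower without dark eid3 replicate 3). The mean of the light signalling list was -0.085 (camera adjusted p = 0.0319; -0.07 with slide as a block; adjusted p = 0.543 with an estimated correlation), and its call ended with slide as a block (camera adjusted p = 0.0612). In the fit without dark eid3 replicate 3 that mean was -0.17 with 2 members lower, and the clock mean turned from 0.11 to -0.09. Flavonoid genes had 1 of 16 lower, F3H (1 higher and 1 lower adjusted over the list alone), and without dark eid3 replicate 3 the list had 1 higher and 1 lower and its mean turned from -0.11 to 0.13. Brassinosteroid genes had 1 of 21 higher, BEE3 with 0.63 ± 0.10 (2 adjusted over the list alone), and touch, wound and rapid stress genes 1 of 32 higher, DREB2A with 1.00 ± 0.16, the same adjusted over the list alone. Both lists depended on dark eid3 replicate 3. Without it the touch list had 7 higher and 1 lower and its mean turned from -0.61 to 0.37, and it gained a call (limma camera adjusted p = 4.45e-05; adjusted p = 0.217 with an estimated correlation). The brassinosteroid mean went from 0.21 to 0.05, with 1 higher and 1 lower, and its list call ended. Ethylene genes had 0 of 22 that passed (0 higher and 1 lower adjusted over the list alone) and a mean of -0.28 (camera adjusted p = 0.0131; -0.30 with slide as a block; adjusted p = 0.675 with an estimated correlation), which became 0.05 without dark eid3 replicate 3, with 1 higher and 1 lower. No member passed among the photoreceptor, shade, auxin, gibberellin, expansin, seed and root lists, over all genes by limma or adjusted over the list alone. These lists too depended on dark eid3 replicate 3. In the fit without it the shade list had 0 higher and 2 lower, with a mean of -0.35 in place of -0.05, and gained a call (limma camera adjusted p = 0.000366; adjusted p = 0.151 with an estimated correlation). The auxin list had 1 higher and 3 lower, with a mean of -0.04 in place of 0.30. Gibberellin genes had 2 and 2 with a mean of -0.13 in place of -0.02, photoreceptors 0 and 1 with -0.14 in place of -0.01, expansins 0 and 1 with -0.03 in place of -0.05, and root markers 1 and 0 with 0.03 in place of 0.14. The seed marker mean was -0.48 in place of -0.06. HY5 had -0.68 ± 0.13 (limma adjusted p = 0.0788, and 0.0123 without dark eid3 replicate 3), HYH -0.36 ± 0.26 (limma adjusted p = 0.79), PIL1 -0.12 ± 0.41 (limma adjusted p = 0.953) and SPA1 -0.04 ± 0.16 (limma adjusted p = 0.965).

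For the interaction limma called 86 genes, 65 higher and 21 lower, 53 of them at least 2-fold. Without dark eid3 replicate 3 it called 872 genes, 639 higher and 233 lower, and all 86 were among them in the same direction. The count was 37, 30 and 46 without dark wild type replicate 1, 2 and 3, 42 and 57 without dark eid3 replicate 1 and 2, 38 and 38 without pulsed wild type replicate 1 and 2, and 26, 54 and 35 without pulsed eid3 replicate 1, 2 and 3. The blocked fit called 6 genes, of which only 2 were among the 86. All 86 kept their direction with a mean signed difference of 1.28 in place of 1.34, while the median SE went from 0.146 to 0.258. Over all genes, called or not, the block moved the interaction by a median of 0.11. Among the genes named here only NAC077 and RPT2 were still called in the blocked fit. None of those 6 genes was a member of a list. NAC077 was above background in 1 of the 4 groups only, so the size of its interaction was not measured. Of the 86 genes, 9 had at least 1 of the 4 groups not above background.

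Light-responsive genes were also compared as a set. The set held the 4248 genes that limma called for the mean light effect of both genotypes and that had a value on every array, 2253 induced and 1995 repressed, each signed by its direction. Their mean signed response was 0.62 in wild type and 0.74 in eid3, a difference of 0.12 (limma fry p = 0.0494; exact two-sided permutation p = 0.18). The permutation test took the score of each array over 400 assignments of genotype within light conditions, with 0.005 as the smallest p possible. These scores still held the genotype difference, so an assignment that exchanges the genotypes on all pulsed arrays measures that difference. Its p therefore decides little on the interaction. Each fit that left out an array chose its own light genes, 8805 without dark eid3 replicate 3, so its values are not over the 4248 genes. In these fits the difference was 0.08 without pulsed wild type replicate 1 and missed the threshold of fry. It also missed that threshold without dark wild type replicate 1 (0.10), dark wild type replicate 2 (0.12), dark eid3 replicate 1 (0.18) and pulsed wild type replicate 2 (0.11). Without dark eid3 replicate 2 it was 0.20. In the fit with slide as a block, the set was another one, 1057 genes with the larger responses 1.17 and 1.45, and over it the difference was 0.27 and passed fry. Over the same 4248 genes, compared through the slides, the difference in response was 0.09. In darkness the score was -0.42 ± 0.01 in wild type and -0.36 ± 0.07 in eid3 (SD, n = 3; exact two-sided permutation p = 0.4, smallest possible 0.1; fry p = 0.0592), and the difference of 0.06 was 0.04 over the same genes through the slides and 0.02 over the other set with slide as a block. Dark eid3 replicate 3 lay at -0.438, below the dark wild type arrays, and dark eid3 replicates 1 and 2 at -0.338 and -0.311, above them. Over sets chosen anew, the difference in darkness was -0.02 without dark eid3 replicate 2 and 0.01 without dark eid3 replicate 1, so these are not values of the 4248 genes. In such fits it passed fry without dark eid3 replicate 3 (0.06), dark wild type replicate 1 (0.09), pulsed wild type replicate 1 (0.07), pulsed wild type replicate 3 (0.06) and pulsed eid3 replicate 3 (0.08). After the pulse the score was 0.20 ± 0.04 in wild type and 0.37 ± 0.00 in eid3 (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible), and the difference was 0.18 over all arrays and 0.13 within slide 3.

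**Figure D3:**
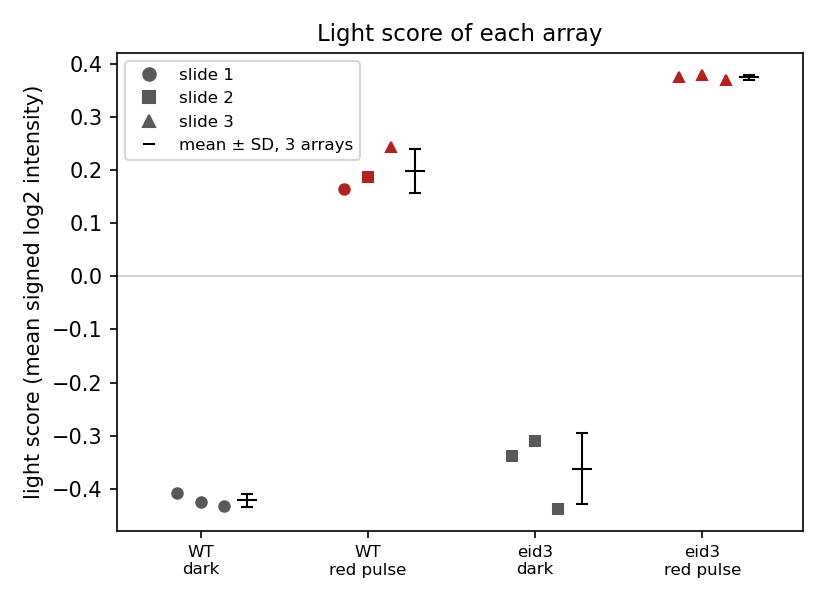
Light score of each array, the mean signed log2 intensity over 4248 light-responsive genes, in the 4 groups, with marker shape for the slide and bars for the mean and SD of 3 arrays. The pulsed eid3 arrays lie between 0.37 and 0.38, above the pulsed wild type arrays at 0.16, 0.19 and 0.24. The dark groups overlap only through dark eid3 replicate 3 at -0.438, while dark eid3 replicates 1 and 2 at -0.338 and -0.311 lie above the dark wild type arrays.

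Genotype differences were also placed along the chromosomes. Among 100 consecutive measured genes at most 66 were called for the mean genotype effect, on chromosome 1 from AT1G62750 to AT1G63970, against a median maximum of 62 in 10000 random draws (one-sided permutation p = 0.0545). Genes called for the mean light effect reached 32 of 100, also the median of the random draws (one-sided permutation p = 0.73). The genotype result missed the threshold here and passed it in 14 of 21 alternatives, with p between 0.0016 and 0.59. Of the 12 fits that left out 1 array 9 passed. Those without dark eid3 replicate 2 (permutation p = 0.305), dark eid3 replicate 3 (permutation p = 0.409) and pulsed wild type replicate 3 (permutation p = 0.0656) did not. Whether called genes cluster is left open.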

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

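The tests on dark eid3 replicate 3, and the slide and replicate tests on the early light-induced genes and on the starting level, the assignment test with mean effects taken out and the slide tests on the interaction, were chosen after the results were seen; the others were written before.

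Each value here was singled out because the light response differed between the genotypes by a test of the interaction. Limma called 86 genes. Smaller responses in eid3, or larger falls, were those of F3H (-2.41), CGA1 (-2.01), RPT2 (-1.93), CKX5 (-1.90), ELIP1 (-1.79), BBX25 (-1.68), SIG5 (-1.68), LHY (-1.24), BBX18 (-0.94) and GUN5 (-0.80). The difference was positive for UGT84A1 (2.37), CYP86A7 (2.16), MAPKKK17 (1.95), BBX22 (1.05), DREB2A (1.00) and BEE3 (0.63). For NAC077 (-5.01) and CIPK20 (3.05) 3 of the 4 groups were not above background, so these are fitted values whose size was not measured; BBX18 was not above background in either dark group. Among lists the mean differences were -0.085 for light signalling regulators, -0.91 for early light-induced chloroplast genes, -0.24 for chlorophyll biosynthesis, -0.30 for light-harvesting complex genes, -0.12 for the photosystem list, -0.28 for ethylene, 0.21 for brassinosteroid and 0.72 for heat shock genes. None of these list calls held with an estimated correlation. With slide as a block the calls of light signalling and light-harvesting genes ended (limma camera adjusted p = 0.0612 and 0.0622). The brassinosteroid mean was 0.05 without dark eid3 replicate 3 and its call ended (limma camera adjusted p = 0.317), and the ethylene mean turned to 0.05. Over all light-responsive genes the difference was 0.12, which passed the fry test of limma and not the exact permutation test (p = 0.18).

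Of 100 assignments of genotype within light conditions, 3 gave at least as many interaction genes as the real one, itself included, and the highest other, with 10528 genes against 86, exchanges the genotypes on all pulsed arrays and so measures the genotype effect. Mixing genotypes puts that effect into the residual spread, whose median rose from 0.169 to 0.25, and 85 of the other assignments called no gene, so this count decides little on chance. With the mean genotype and light effects taken out first, the residual spread was alike (0.165), 1 of 100 assignments gave as many genes, the real one, and the highest other gave 1. That argues against chance assignment. With slide as a block the fit called 6 genes, of which only 2 were among the 86. The 86 genes kept a share of 0.957 of their mean signed interaction (1.28 against 1.34) and all 86 their direction. Their median SE went from 0.146 to 0.258 with residual degrees of freedom down from 8 to 6, so the calls ended through the error. Called genes had pulsed wild type arrays close together across the slides, which favours a high share. Over all 23601 genes with a value on every array, called or not, the block moved the interaction by a median of 0.11, and by 0.125 over the called ones, against their median size of 1.09. For most of the called genes as chosen, these medians argue against a large shift by slide. In the upper tail over all genes the shift was 0.926, near the median size of a called interaction. Because the choice of called genes favours a small shift, these values do not exclude slide as a source of some calls. Each slide also held only 1 pulsed wild type array to link it. For the wild type light response (1891 genes, highest other split 1), the eid3 light response (2866, highest other 1), the genotype difference in darkness (7393, highest other 0) and after the pulse (6571, highest other 0), 1 of 10 splits gave as many genes, the real one. With 10 splits a share under 0.05 cannot be reached.

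The smaller response of early light-induced chloroplast genes in eid3 was weighed against slide, against dark eid3 replicate 3 and against a ceiling of the signal. The list mean was -0.82 with slide as a block and -0.81 without that array, so neither accounts for most of it. At least 372 genes were measured in pulsed eid3 above the level that each called member would have reached, which argues against a ceiling of the array signal. A limit of a member's own probe is not tested by this count. A candidate explanation that stays open for the list is that these genes, already higher in dark eid3, had less left to gain. By itself it does not give the value of SIG5, a called member that was lower in eid3 than in wild type after the pulse. Most members called for the genotype difference after the pulse were higher in eid3.

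That idea was tested over 2253 light-induced genes, with the dark difference and the interaction taken from different arrays. The rank correlation was -0.338 and -0.275 in the 2 directions of the test, and -0.298 and -0.261 within slides, so slide does not account for it. Genes are not independent replicates. The first 2 values met the rule written beforehand for a starting level, but that rule cannot single out this cause. The interaction contains the dark difference with a minus sign, also when it comes from other arrays. Any dark difference that the pulsed arrays do not carry in full gives a negative correlation, whatever its cause. Genes without a light response were not run beside these. By dark difference, the lowest 1/3 of the genes had mean interactions of 0.311 and 0.328, and the highest 1/3 had -0.0618 and 0.011. The middle 1/3 was not summarized, so which genes carry the correlation was not tested. Over these genes a higher starting level in eid3 went with a smaller response relative to the lowest 1/3, and on average with about the wild type response. Whether it accounts for the early light-induced genes stays open, and a change in light signalling in eid3 was not tested separately.

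Dark eid3 replicate 3 stood apart from its group. Deviations of different probes of a gene correlated by 0.921, which argues against noise of spots. Its slope on the genotype difference was 0.873, beside 0.864 and 0.880 for the other 2, which argues against a sample of the other genotype. The touch, wound and rapid stress list lay at the 100th percentile of random lists, so handling or another stress before harvest may have set it apart. Auxin, shade and seed genes also moved there, and a difference in growth of that sample stays open and untested.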

How the results depend on the processing

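Array quality weights and slide as a block without dark eid3 replicate 3 were chosen after the data had been seen. The cause of the changes below was not tested, except where fewer arrays or a stricter threshold give it by construction. Each alternative fit chose its own genes for the light score, so its score values are over differing sets.

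Stricter thresholds left, at least 2-fold and at an adjusted p under 0.01, 643 and 1002 genes for the wild type light response, 938 and 1456 for eid3, 1933 and 3995 for darkness, 1638 and 3631 after the pulse, and 53 and 23 for the interaction. Fits over the 2 groups gave 3103, 1359, 3094 and 12004 in the first 4 contrasts. With slide as a block the counts were 671, 440, 545, 2447 and 6. With slide as a block and without dark eid3 replicate 3 the counts were 3364, 2275, 5302, 9328 and 114. Array quality weights gave 8942, 11573, 16350, 14639 and 4689; the weight estimation gave a convergence warning, with weights from 0.0265 for dark eid3 replicate 3 to 8.44 for dark wild type replicate 2. With no filter on dim probes the interaction was 39.

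With the replicate block the interaction was 32, the light score response 0.1193, which missed the threshold, and the clustering 66 of 100, which passed it. Of 18 same-numbered pairs 3 correlated over 0.1, and 5 of 12 arrays correlated best with their own number, so the numbers are not taken as pairs.

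The light score difference in response missed the threshold with quantile normalization (0.1137), a filter on all 12 arrays (0.1049), each probe tested separately (0.1044) and the series table (0.1176). The difference in darkness passed with quantile normalization (0.05937), a filter on all 12 arrays (0.06314) and each probe tested separately (0.0742). Clustering passed with no filter on dim probes (55), a filter on all 12 arrays (67), slide as a block (36) and eBayes with trend and robust (67).

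Leaving out 1 array at a time gave 1161 to 5673 genes for the wild type light response, 1664 to 6563 for eid3, 5186 to 11744 for darkness, 4289 to 12490 after the pulse and 26 to 872 for the interaction. The ranges were 0.08127 to 0.1998 for the light score response, -0.01775 to 0.09345 for its difference in darkness, 45 to 49 for the list tests called and 60 to 81 for clustering. The highest counts of genes were those without dark eid3 replicate 3.

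HFR1, not called in either contrast, changed sign in darkness without dark eid3 replicate 3 (0.4136; leaving out 1 array gave -0.276 to 0.4136) and with array quality weights (0.3761), and in the interaction with array quality weights (-0.3962). Without dark eid3 replicate 3 the touch list in darkness (-0.08754, range -0.08754 to 1.39 leaving out 1 array) and the ethylene list in the interaction (0.04968, range -0.4605 to 0.04968) changed sign. Of the list shifts 939 comparisons kept side and direction and 25 lost the call. Of the named gene values 4698 kept both, 236 lost the call and 42 gained it. Signal over background limits the dim genes, where 63, 103, 274 and 140 calls of the first 4 contrasts had 1 side not above background, and 9 of the interaction had at least 1 of 4 groups not above it.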

Other observations

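The test of probe mismatch and the test of slide in darkness were written before their results were seen, and no test in this part was chosen after.

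Light-responsive genes were spread over both directions of the genotype difference. Of 2278 genes induced by light over both genotypes, 530 were higher and 482 lower in dark eid3, and of 2010 repressed genes 355 were higher and 530 lower. These were 23.3 and 21.2 percent of the induced and 17.7 and 26.4 percent of the repressed genes, against 12.2 and 18.7 percent of all genes. In the fit without dark eid3 replicate 3, 1048 of 3625 induced genes were higher and 1077 lower, 28.9 and 29.7 percent against 22.9 and 26.3 percent of all genes, and of 5258 repressed genes 1141 were higher and 1747 lower. Light responses of the genotypes correlated over all genes with r = 0.666 and a rank correlation of 0.514, where genes are not independent replicates. In the interaction 49 of the induced genes were higher and 17 lower in eid3, which without dark eid3 replicate 3 were 427 and 85 of 3625.

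Sequence differences between the lines could make a probe bind less in 1 line. If so, another probe of the same gene would often disagree. Among 2609 genes called for the mean genotype effect with another probe, 96.36 percent had the same direction there, and 298 of 299 genes with at least a 2-fold effect, which argues against this as the main source.

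Slide could add to the genotype difference in darkness, because the dark groups lay on different slides. The pulsed wild type arrays of the same slides showed a share of 0.0146 of the mean difference over 7327 called genes, with 52.15 percent in the same direction. For the mean over these called genes, this argues against slide as the main source, although each slide held only 1 such array. The choice of called genes favours pulsed wild type arrays that agree across slides, and so a low share. Over all genes the block for slide moved the difference by a median of 0.0989, and by 0.834 in the upper tail. The median size of a called difference was 0.62, and the blocked fit called 545 genes in place of 7393. Slide is therefore not excluded as a source of some calls.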
